A study of Mus musculus with 6 samples.

How the data were processed

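Gene expression was measured in ovarian surface epithelium, the single cell layer that covers the ovary, from female Lgr5-eGFP-CreERT2 mice aged 8 to 12 weeks. In this line EGFP is expressed from the Lgr5 locus. Per the labels, cells were sorted by flow into an EGFP-high and an EGFP-low population, with material of 8 mice pooled for each array. There were 3 arrays for each population. Per the series' design text the 3 are technical replicates. The p-values of single genes therefore measure the spread between arrays, which may be technical, and not the spread between animals. RNA was amplified with a NuGEN pico-scale whole-transcript kit and hybridised to Affymetrix Mouse Gene ST 2.0 arrays.

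The authors deposited log2 expression values for 41345 probe sets on each of the 6 arrays, with array medians from 3.76 to 3.85. Affymetrix Expression Console and RMA (background correction, quantile normalization and probe set summary) are named, without versions, in the submitters' processing notes. The genome build and the annotation were not given in the sources used here. The authors also deposited a comparison table of 1134 probe sets with a linear ratio of high over low, a signed fold and sums of squares, all at 1.5-fold or more. Its p-values are blank in every line and its error sum of squares is at most 4.55e-13, per the file itself, so it was used for folds alone. No column of per-sample values was left without a sample (0 such columns).

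The deposited log2 columns obeyed 2 linear relations across all 41345 probe sets, to within a tolerance of 2e-04. High replicate 2 equalled the mean of high replicates 1 and 3, with an SD of 4.75e-06. Low replicate 1 equalled the mean of low replicates 2 and 3 plus 0.75 times the difference of high replicate 3 minus high replicate 1, with an SD of 6.21e-06. The 6 columns therefore hold 4 independent dimensions. No source used here states a step that would give these relations. Of 201 ways to part the 6 arrays into 2 to 5 sets, 1 gave exactly both relations when removed by least squares with the group means kept: low 1 with high 1, low 2 and low 3 with high 3, and high 2 alone. These are called array sets below. They are inferred from the values and are in no label.

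Probe sets were named from the platform annotation supplied for this work. Of the probe sets, 23521 had 1 gene symbol, 1820 had several and 16004 were unlisted and stay unnamed. For 23328 of those with 1 symbol, the Entrez identifier was found in a RefSeq gene table (GRCm38.p6), which was used only for older symbols. For 1082 genes with more than 1 probe set the one with the highest mean over the 6 arrays was taken, which left 22180 genes. The probe sets of 458 of those genes differed in the sign of the fold. No filter on dim genes was applied and no further normalization was done.

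High minus low was tested on the log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over genes, threshold 0.05). The fit chosen before the data were examined had group as its only term and 4 residual degrees of freedom. The same fit with the array set as a further term has 2, which is what the 4 dimensions allow. It was chosen after seeing the data. Fold changes are the same in both. Intervals are 95% limits from the fit with the array-set term, not adjusted for the number of genes. For second probe sets, and for those named from the authors' table, that fit was run over all probe sets. The limits differ between the 2 runs: the main Lgr5 probe set has 0.56 to 1.63 over all probe sets and 0.62 to 1.57 over genes. For each gene, 2 contrasts within the inferred array sets are also given. They are separate only if the array-set removal took place. The first is high 1 minus low 1. The second is high 3 minus the mean of low 2 and low 3. Verbs of change are used only for calls made with the array-set term.

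Gene lists (32) were fixed before the data were examined and tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists. At that preset, camera compares the genes of a list with the other genes, so its p-value measures spread over genes under the assumed correlation. That p-value does not measure the spread between arrays or animals. Camera with an estimated correlation and fry were run beside the preset form. Both rest on the residual degrees of freedom of the arrays, 2 with the array-set term and 4 with group alone. Genes named in the text were taken by a rule also fixed then. It takes Lgr5, the 15 largest folds in each direction among genes past the threshold of the group-only fit whose arrays do not overlap, up to 4 members of each list with the smallest p, and 9 marker genes. Predicted genes, small RNAs, immunoglobulin segments and olfactory receptors were left out of the 15. A list member was matched through an older name only if its symbol is not itself a current one. This was set after the data were seen, when complement C3 had been matched to an olfactory receptor gene through an older name.

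The fits were tested on 20 simulated data sets of 22180 genes, with the real gene means, spreads drawn from the array-set fit, and the same least-squares removal. With no gene changed, the group-only fit called a mean of 971 genes (719 to 1075) and the fit with the array-set term called a mean of 0.10. With 200 genes changed, the fit with the array-set term recovered 7.58% of changes of 1 on the log2 scale, 90.4% of changes of 2 and 99.1% of changes of 3. The group-only fit recovered 83.0%, 98.7% and 99.8%.

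Alternatives were quantile normalization, median centring, a filter on dim genes, the average of probe sets, all probe sets, the replicate number as a block, trended and robust variances, array weights, a per-gene test without shared variances, the authors' table, other thresholds, and leaving out each array. Removal of a smooth trend (lowess) of the fold on mean expression was added after seeing the data. Their effects are given in the closing section. Coordinates were not used here, because the build of the array annotation was not named.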

Results

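Transcript levels were compared between EGFP-high and EGFP-low cells of the mouse ovarian surface epithelium. EGFP was expressed from the locus of Lgr5, a Wnt-associated receptor that marks stem cells in several epithelia. There were 3 arrays per population, with 8 mice pooled per array and 22180 named genes tested. The comparison asks how the transcriptome of Lgr5-expressing surface cells differs from that of cells sorted as EGFP-low. The 6 deposited columns hold 4 independent dimensions, and high replicate 2 is the mean of high replicates 1 and 3, so the high population is represented by 2 independent columns. By the 2 relations, each difference of group means also equals high replicate 3 minus low replicate 1. The 6 readings given for a gene are therefore not 6 separate ones.

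Lgr5 was higher in the EGFP-high cells by 1.10 on the log2 scale (95% interval 0.62 to 1.57). Its 3 high arrays read 8.996, 8.97 and 8.94, and its 3 low arrays read 7.84, 7.76 and 8.01. A second Lgr5 probe set differed by 1.48 (0.96 to 2.01). Sorting was on this locus, so the difference checks the labels and is no independent finding. A permutation test of the 3 against 3 Lgr5 values gave p = 0.10, the smallest that this design allows. That p is nominal, because the column relations mean that the arrays are not exchangeable. In simulated data with no changed gene, 30.6% of genes had groups that did not overlap, which gives this smallest p. Limma gave an adjusted p of 0.015 with group alone and 0.751 with the array-set term.

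Cyp11a1, which encodes the enzyme that converts cholesterol to pregnenolone in the first step of steroid synthesis, fell by 4.74 on the log2 scale in the EGFP-high cells (interval −5.49 to −3.99). It was the only gene past the threshold with the array-set term, with a limma adjusted p of 0.014, and the next gene was at 0.459. Its 3 low arrays read 9.09, 8.26 and 8.92 against 3.68, 4.02 and 4.35 in the high arrays. A dimmer probe set of Cyp11a1 differed by only −0.17. With that probe set averaged in, or with all probe sets tested, limma called 0 genes with the array-set term (smallest adjusted p 0.433 and 0.337). At an unadjusted p under 0.05 the fit on genes had 1314, where chance gives 1109. Without high replicate 3 that fit called 23 genes, all lower, and without low replicate 3 it called 3.

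**Figure D1:**
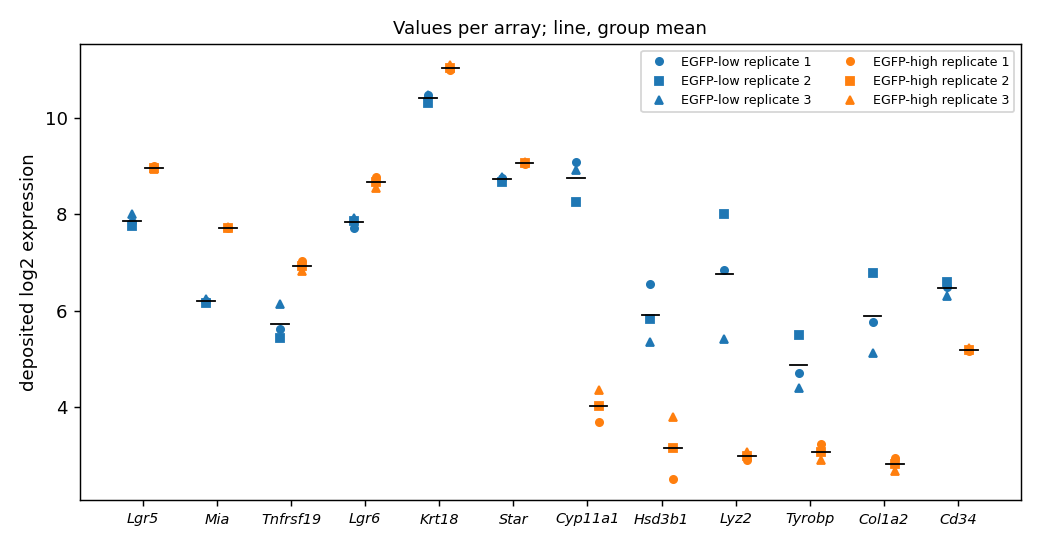
Deposited log2 expression of 12 genes on each of the 6 arrays (vertical axis, log2), with low arrays in blue, high arrays in orange, replicates by marker and a line at each group mean. Lgr5 is 1.10 higher and Cyp11a1 4.74 lower in the high arrays, and high replicate 2 sits midway between high replicates 1 and 3 for every gene.

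The fit with group alone called 1479 genes, 865 higher and 614 lower, of which 538 differed by at least 1.5-fold (278 higher, 260 lower). Centring each array on its median moved the split to 1481 higher and 474 lower. The group-only count is not read as a number of changed genes, because data simulated with the same column relations and no changed gene gave a mean of 971 calls. Arrays of the 2 populations did not overlap for 7364 genes (33.2%), against 10% by chance for 3 against 3 independent arrays and 30.6% in that simulation. Over the 22180 genes the 2 contrasts within array sets correlated with Pearson's r = 0.18 and Spearman's rho = 0.14, a value across genes, which are not independent replicates. Of 489 genes at 1.5-fold or more in both contrasts, 368 (75.3%) had the same sign. The simulation with no changed gene gave r between −0.015 and 0.011 and the same sign for 49.6% of such genes. It had a mean of 592.9 such genes against the 489 observed. The simulation draws each gene independently, so it cannot show what variation shared between genes would give. The correlation and the share of equal signs also rest on the inferred array sets, since low 1 is a combination of columns that the second contrast uses.

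**Figure D2:**
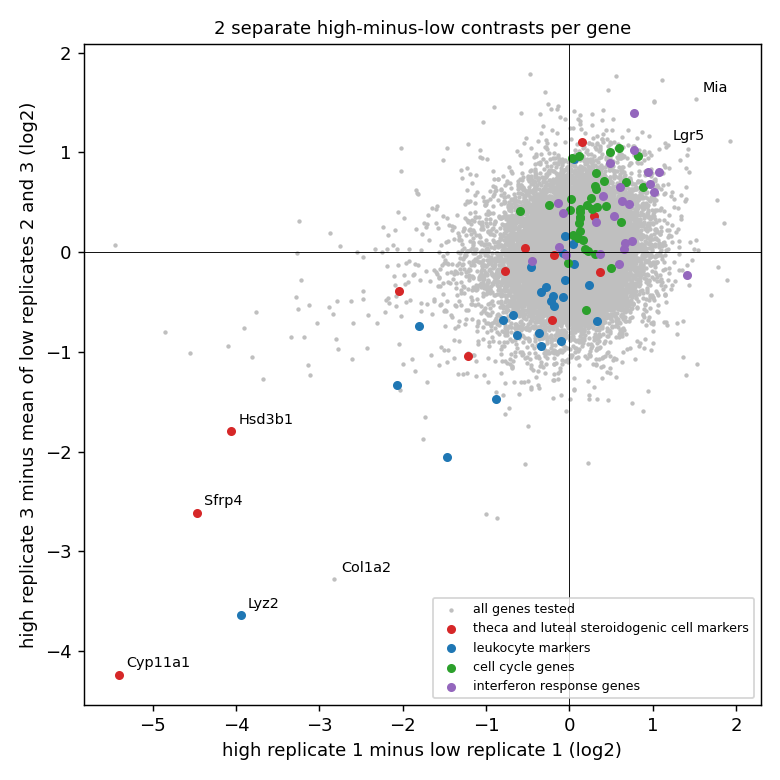
High minus low for every gene in each of 2 contrasts within inferred array sets (log2): high 1 minus low 1 on the horizontal axis and high 3 minus the mean of low 2 and low 3 on the vertical axis. Points are genes, coloured for 4 fixed lists, and Cyp11a1 lies at −5.41 and −4.24 while most genes scatter around 0 (r = 0.18).

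Among named genes with the largest positive differences, Mia, a secreted protein first described in melanoma, was 1.53 higher (1.07 to 1.98), with 1.52 and 1.53 in the 2 contrasts. Slfn2 and Apol7e were each 1.46 higher. The POU-domain transcription factor Pou2f3 was 1.30 higher, as was Tceal6. The TNF receptor family member Tnfrsf19 (Troy) was 1.20 higher (0.59 to 1.81), and the LIM homeobox gene Isl1 1.12 (0.64 to 1.60). Usp18 (1.13), Shcbp1 (1.12), Myl9 (1.10), Ndst4 (1.06), Id1 (1.01), Clec2l (1.001) and Fcgr2b (0.997) completed the 15 with Lgr5. All were higher in both contrasts, but the rule that picked them requires arrays that do not overlap. That fixes the sign in advance, so the shared sign is no support. None passed the adjusted threshold with the array-set term (limma adjusted p from 0.464 for Mia to 0.751).

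Negative differences were larger. Lyz2, the lysozyme of macrophages and neutrophils, was −3.77 (−5.26 to −2.28), and Sfrp4, a secreted frizzled-related protein, was −3.41 (−4.65 to −2.17). The type I collagen chain Col1a2 was −3.08 (−4.10 to −2.06), although a second Col1a2 probe set gave −0.78. Hsd3b1, which makes progesterone from pregnenolone, was −2.76 (−3.84 to −1.69), and the HLH inhibitor Id2 was −2.30 (−3.42 to −1.18). Mmp2, a gelatinase, was −1.69 in a narrow interval (−2.16 to −1.21). Acsbg1 (−2.03), Dppa3 (−1.93), Tyrobp (−1.81), Gsg1l (−1.74), Cyp1b1 (−1.73), Frmd5 (−1.70), Pf4 (−1.66) and Vldlr (−1.59) made up the rest. Apart from Cyp11a1 these missed the adjusted threshold with the array-set term, the lowest limma adjusted p being 0.459 for Mmp2.

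Of the 32 gene lists, camera called 16 with the array-set term (7 up, 9 down) and 17 with group alone (7 up, 10 down). With an estimated correlation it called 0, with smallest adjusted p = 0.286 and 0.140. Fry, which asks whether a list moves one way, called 0 with the array-set term (smallest adjusted p 0.120) and 18 with group alone. Its mixed form, which counts change either way, called 4 with the array-set term, the surface epithelium, epithelial-mesenchymal transition, TGF-beta and oxidative phosphorylation lists. Counts of single list members below are with the array-set term. With group alone the members past the threshold, higher and lower, were 1 and 3 of 12 theca and luteal markers, 0 and 8 of 27 leukocyte, 1 and 4 of 21 stroma, 1 and 6 of 25 oocyte, and 3 and 4 of 28 TGF-beta genes. They were 3 and 0 of 24 stem cell genes, 3 and 0 of 27 surface epithelium markers, 8 and 0 of 36 cell cycle, 8 and 0 of 24 interferon, and 5 and 1 of 29 Wnt genes.

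Steroidogenic genes fell as a list by camera, but not by fry with the array-set term (adjusted p = 0.246). Their mean of −1.11 was further from 0 than their median. The list of theca and luteal steroidogenic markers had a median of −0.46 over 12 measured genes, 9 below 0 and 3 above, and 5 were lower by at least 1.5-fold. Camera gave an adjusted p of 7.68e-06 with the array-set term, and adjusted p = 0.286 with an estimated correlation. Singly, 4 genes fell adjusted over the list alone, against 1 over all genes. The change was not shared by all members: Star, which carries cholesterol into mitochondria, read 8.74 in the low and 9.07 in the high population and differed by 0.33 (−0.12 to 0.79). In the authors' deposited table the receptors Lhcgr and Prlr stand on probe sets that the annotation pairs with several symbols. They were chosen after their values were seen, and their value-table differences were −3.98 (−5.96 to −1.99) and −2.75 (−4.48 to −1.03).

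Leukocyte markers fell too, with a median of −0.38 over 27 genes, 23 of them below 0 and 10 lower by at least 1.5-fold (camera adjusted p = 5.15e-09, and adjusted p = 0.323 with an estimated correlation). Singly, 6 fell adjusted over the list alone and 0 over all genes. Among its members were Lyz2 (−3.77), Tyrobp (−1.81), the complement gene C1qb (−1.22, −1.85 to −0.59) and Cd53 (−0.73). The pan-leukocyte gene Ptprc read 2.43 and 2.06 in the low and high populations. Markers of ovarian stroma and fibroblasts fell with a median of −0.22 over 21 genes, 14 of them below 0 (adjusted p = 0.0033, and adjusted p = 0.320 with an estimated correlation). Of these, 2 fell adjusted over the list alone and 0 over all genes. Col1a2 and Cd34 (−1.27, −1.76 to −0.79) led this list, while Thy1 was 0.53 higher and Col1a1 differed by −0.45 (−1.14 to 0.23).

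Oocyte markers had a median of −0.22 over 25 genes and fell by camera (adjusted p = 0.0010, and adjusted p = 0.286 with an estimated correlation). There were 3 that fell adjusted over the list alone and 0 over all genes. Zp2 (−0.90) and Nlrp5 (−0.79) had means of 3.56 and 3.90 in the low cells, and the call ended when genes below the median brightness were left out (adjusted p = 0.719). Adipocyte markers fell with a median of −0.23 over 14 genes (adjusted p = 0.0033, and adjusted p = 0.286 with an estimated correlation), with 0 past the threshold both adjusted over the list alone and over all genes. That call was lost without low replicate 1 or high replicate 1 (adjusted p = 0.164), which with the array-set term are 1 and the same fit.

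Epithelial stem and progenitor cell genes rose, with a median of 0.21 over 24 genes, 18 of them above 0 (camera adjusted p = 0.0017, and adjusted p = 0.320 with an estimated correlation). Lgr5, Tnfrsf19 and Lgr6 were the 3 that rose adjusted over the list alone, and 0 rose over all genes. Lgr6, a paralogue of Lgr5, was 0.83 higher (0.34 to 1.31), and Tert was 0.53 higher (0.02 to 1.05). Lgr5 belongs to this list and was sorted on, and camera was not run without it. The naming rule took the 4 members with the smallest p, so none of the 6 members below 0 is named. In the fit without low replicate 1, which is also the fit without high replicate 1, the call was lost (adjusted p = 0.0712). Genes of the Wnt pathway were not called (adjusted p = 0.342): their median was 0.10 but their mean −0.02, and camera's direction was up. Axin2, a direct Wnt target, differed by 0.45 (−0.01 to 0.91; second probe set 0.31, −0.23 to 0.85), and Sp5, another target, by 0.58 (0.12 to 1.03), beside −3.41 for Sfrp4. Lgr5 was the 1 Wnt gene that rose adjusted over the list alone, and Sfrp4 the 1 that fell.

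Surface epithelium and mesothelium markers rose slightly and together, 25 of 27 above 0 with a median of 0.20 (camera adjusted p = 0.00023, and adjusted p = 0.286 with an estimated correlation). The call ended when a trend of fold with brightness, looked for after seeing the data, was removed (median 0.07, adjusted p = 0.0826). That outcome turns on a correction made after seeing the data: with an olfactory receptor gene wrongly matched as C3, adjusted p = 0.0480. None was past the threshold on its own, adjusted over the list alone or over all genes (0 in each). Krt18 differed by 0.62 (0.15 to 1.09), Cdh1 by 0.54 (0.09 to 0.998) and Dmkn by 0.56 (0.09 to 1.03). Second probe sets gave 0.36 for Krt18 (−0.24 to 0.96) and 0.30 for Cdh1 (−0.32 to 0.93). Krt8 (0.30, −0.19 to 0.80), Krt19 (0.27, −0.22 to 0.77) and Wt1 (0.20, −0.27 to 0.67) had intervals that span 0.

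Cell cycle genes rose with a median of 0.31 over 36 genes, 33 above 0 (camera adjusted p = 3.87e-08, and adjusted p = 0.286 with an estimated correlation). None passed singly, adjusted over the list alone or over all genes (0 in each). The helicase subunits Mcm3 (0.90, 0.44 to 1.36) and Mcm5 (0.58, 0.11 to 1.05), the mitotic kinase Ttk (0.76, 0.29 to 1.22) and Ube2c (0.69, 0.22 to 1.15) were among its members. Mki67 differed by 0.03 in the first contrast and 0.94 in the second. Interferon response genes had the largest positive median, 0.45 over 24 genes with 21 above 0 (adjusted p = 1.63e-08, and adjusted p = 0.286 with an estimated correlation). In it, 4 rose adjusted over the list alone and 0 over all genes. Usp18 was 1.13 higher, Isg15 0.92 (0.38 to 1.46), the immunoproteasome subunit Psmb8 0.92 (0.38 to 1.46) and Irf9 0.63 (0.17 to 1.09).

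**Figure D3:**
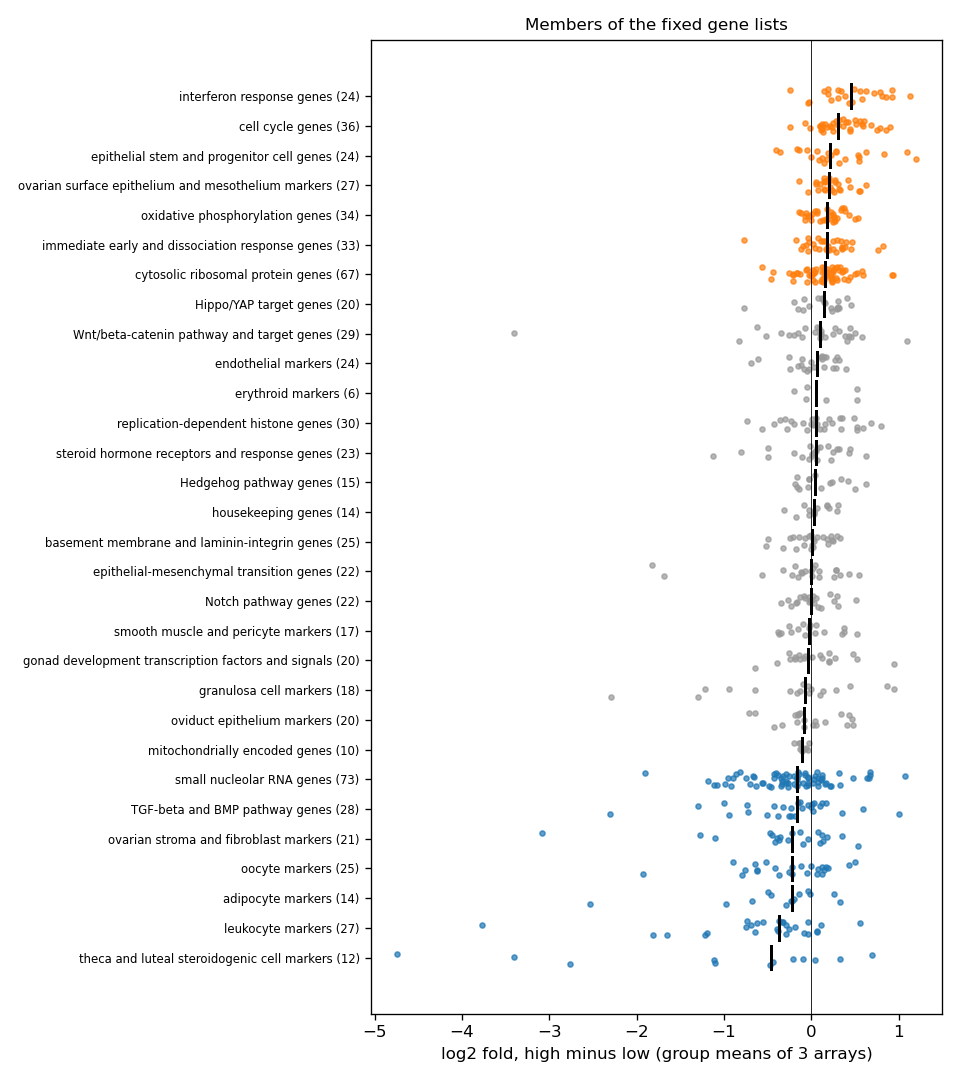
Log2 fold, high minus low, of each member (points) of 30 fixed gene lists, with the number of measured members in brackets and the list median as a black line. Lists called by camera with the array-set term are orange (up) or blue (down) and others grey; interferon genes have a median of 0.45 and steroidogenic markers of −0.46.

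TGF-beta and BMP pathway genes fell with a median of −0.17 over 28 genes (camera adjusted p = 0.0030, and adjusted p = 0.320 with an estimated correlation). The members did not move one way: Id1 rose (1.01) and its relative Id2 fell (−2.30) adjusted over the list alone, and Skil, a repressor of the pathway, was −0.73 (−1.18 to −0.28). Immediate early genes (median 0.18 over 33), oxidative phosphorylation genes (0.18 over 34) and cytosolic ribosomal protein genes (0.16 over 67) rose by camera (adjusted p = 0.0080, 0.0046 and 0.0033, and adjusted p = 0.592, 0.286 and 0.5996 with an estimated correlation). Ccn2, a connective tissue growth factor in the first of these lists, went against it at −0.77 (−1.25 to −0.28), with −0.09 (−0.68 to 0.50) from a second probe set. Removal of the brightness trend ended all 3 calls (medians 0.06, 0.05 and 0.04, adjusted p = 0.461, 0.455 and 0.231). Quantile normalization ended the calls of immediate early (adjusted p = 0.228) and oxidative phosphorylation genes (0.198), as did leaving out genes below the median brightness (0.145 and 0.103). Without high replicate 3 camera called none of these 3 lists (0.161, 0.128 and 0.394), and without low replicate 2 the immediate early list was lost (0.136).

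Small nucleolar RNAs (median −0.17 over 73), microRNA genes (−0.12 over 483) and olfactory and vomeronasal receptor genes (−0.10 over 1390) fell by camera (adjusted p = 1.51e-04, 7.55e-05 and 2.26e-04, and adjusted p = 0.286, 0.286 and 0.390 with an estimated correlation). The small nucleolar call was lost in the 1 fit that leaves out low replicate 1 or high replicate 1 (0.112), and the olfactory call ended when the brightness trend was removed (median −0.04, adjusted p = 0.397). In these 3 lists and the 3 before them, 0 members passed adjusted over the list alone.

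Besides the Wnt list, 15 lists were not called by camera with the array-set term (adjusted p from 0.206 for mitochondrially encoded genes to 0.939 for Notch genes). Endothelial markers had a median of 0.07 over 24 genes, and Pecam1 differed by 0.27 (−0.19 to 0.72). Smooth muscle and pericyte markers had a median of −0.03, oviduct epithelium −0.08 and erythroid markers 0.06 over 6 genes. Haemoglobin genes are not in that erythroid value. Probe sets named Hba-a2 and Hbb-b1 in the authors' deposited table, chosen after their values were seen, differed by −2.06 and −0.93 and by −2.18 and −2.02 in the value table. Granulosa markers had a median of −0.07 and were called only without high replicate 3 (camera adjusted p = 0.0051), where high minus low rests on high 1 against low 1. They went both ways: adjusted over the list alone 2 were higher, including Nr0b1 (0.94, 0.45 to 1.44), and 3 lower, including Fst (−1.29, −2.12 to −0.46). Medians were −0.03 for gonad development genes, 0.05 for Hedgehog, −0.01 for Notch, 0.15 for Hippo, 0.01 for basement membrane and 0.06 for steroid receptor genes. They were 0.03 for housekeeping, 0.06 for histone and −0.10 for mitochondrially encoded genes, which were called with group alone (0.0362). Means differed in sign from medians for gonad (0.03), Notch (0.02), basement membrane (−0.01) and steroid receptor genes (−0.01). Nr0b1 was the 1 gonad gene past the threshold adjusted over the list alone. Epithelial-mesenchymal transition genes had a median of 0.00 and a mean of −0.13, with Mmp2 the 1 member that fell adjusted over the list alone.

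The authors' deposited table held 505 probe sets higher and 629 lower in the EGFP-high cells. All 1134 had the sign of the fold from the value table, and the log2 ratios correlated across probe sets with r = 0.986. The listed probe sets were chosen for a fold of at least 1.5 in the same comparison. The shared sign and the high r were therefore largely fixed in advance. The value table itself held 3926 probe sets at 1.5-fold or more, which included 806 of those listed. With the array-set term, 544 of the 1134 had an unadjusted p under 0.05 and 0 of all probe sets passed after adjustment.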

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

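The array-set term, the fit without high 2 and low 1, and all alternatives run with the array-set term were chosen after seeing the data; the others were planned.

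Against 1479 genes called with group alone, the replicate number as a block gave 4, the array-set term 1, and leaving out high 2 and low 1 together 1. Fewer residual degrees of freedom are part of each of these fits. Array weights gave 20529, with weights of 157 on high 2, whose deviations from its group mean are near 0 by the column relations, and 27.8 on low 1; the cause of the latter was not tested. An unadjusted p under 0.05 with at least 1.5-fold gave 970, and an adjusted p under 0.1 gave 3342, by construction. Leaving out each array gave 0 to 2583: 0 without low 1, high 1, high 2 or high 3, 2583 without low 2 and 2326 without low 3. With 1 array fewer the residual degrees of freedom also fall; why low 2 and low 3 go the other way was not tested. All 1479 kept their sign in the fits that measure them, except 1 when probe sets were averaged (1478).

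Against 538 genes at 1.5-fold or more, the filter on dim genes gave 347 (fewer genes tested), all probe sets 1013 (more features tested), the replicate block 4 and array weights 1536. An equal-variance test per gene with no shared variance gave 261, and its cause was not tested. The array-set term gave 1, high 2 and low 1 left out 1, leaving out each array 0 to 877, and the authors' table, which has no test, 1134.

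The Lgr5 difference of 1.10 was 1.10 with the replicate block (adjusted p 0.117), 1.10 with the array-set term (0.751) and 1.08 without high 2 and low 1 (0.679). Leaving out each array gave 1.04 to 1.17. Camera's 17 lists with group alone became 0 with an estimated correlation (the cause was not tested), and 15 to 17 with each array left out.

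With the array-set term, the 1 gene called became 0 with the average of probe sets and 0 with all probe sets, the first because a dim Cyp11a1 probe set is averaged in. With all probe sets the unadjusted p of Cyp11a1 was 4.12e-05 against 6.33e-07, and the cause was not tested. The 1 gene became 1 to 23 with each array left out (23 without high 3, 3 without low 3; the cause was not tested). The 16 lists became 0 with an estimated correlation and 0 with fry (the cause was not tested). A correlation above the preset 0.01 is argued against as the cause for oxidative phosphorylation, microRNA and adipocyte genes. Their estimates were −0.021, 0.0061 and 0.0036, yet unadjusted camera p rose from 0.0022, 1.18e-05 and 0.0014 to 0.072, 0.033 and 0.080. The other called lists had estimates above 0.01. With each array left out, 13 to 16 lists were called. Cell cycle, interferon, leukocyte, steroidogenic, stroma, surface epithelium, TGF-beta, oocyte, microRNA and olfactory lists stayed called in all 6 of those fits, of which 4 differ: leaving out high 2, alone in its array set, changes nothing, and leaving out low 1 or high 1 is 1 and the same fit.

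Of 147 named genes, 54 stayed on their side of the threshold with the array-set term and 93 lost it. The 1 reversal was Oog1, an oocyte gene, from 0.50 to −0.32 when its probe sets were averaged, because its other probe set gave −1.14. Whether replicate numbers pair the arrays is not shown: correlations of deviations from the group mean were −1, −0.0065 and −0.295 for replicates 1 to 3, and the column relations fix the first and leave rounding (SD 2.91e-06) for high 2. Low signal limits the dimmest genes: the oocyte call ended when only brighter genes were kept. On the high arrays 5 of its 25 members are brighter than the median gene, which is not the count of members in that fit.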

Other observations

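The tests of the column relations and of brightness, the simulation, both tests of a lower share of the main cell type, and the splits with the array-set term were chosen only after the result was seen; the splits with group alone were planned, and the further marker genes were listed after the pattern but before their own values were seen.

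The 6 deposited columns obey 2 exact linear relations. A candidate explanation is that a 3-level array set was removed by least squares before deposit: of the 3-set partitions tried, 1 gives both relations. High 2 being filled in with an average and nothing else is argued against by the low arrays, whose own relation holds to an SD of 6.21e-06. The calls with group alone may largely follow from the degrees of freedom so lost, since simulated unchanged genes gave a mean of 971.15 calls against 1479. What the array sets were, and whether animals or sorts differed between them, stays open, as does the part of the 1479 that is biological.

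The 6 arrays make too few splits (10, or 9 that can be fitted with the array-set term) for a share under 0.05. With group alone, 1 split of 10, the real one, called as many genes (1479, highest other 0), as many at 1.5-fold (538, highest other 0) and as many lists (17, highest other 16). The split with 16 lists puts low 1, high 1 and high 2 against low 2, low 3 and high 3. By the column relations its difference is a fixed fraction of the real high minus low for every gene. It therefore carries the real contrast and is no measure of chance, and it cannot be fitted with the array-set term. With that term, 1 split of 9, the real one, called as many genes (1, highest other 0) and as many lists (16, highest other 14). The split with 14 lists puts low 1 against high 1, as the real one does.

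Steroidogenic and leukocyte markers were lower in EGFP-high cells (median −0.38 over 39 members), and stroma (−0.22), oocyte (−0.22) and adipocyte (−0.23) markers and the haemoglobin probe sets were lower too. Among members brighter than the median gene in either population, medians were −0.35 for stroma and −0.57 for adipocyte markers. The brighter oocyte markers had a median of 0.006 over 6 genes, so that list was lower only through dim genes. A lower share of the main cell type in EGFP-low, raising all other types alike, stays open: the 2 lists differed from the 8 other cell-type lists (permutation p 4.70e-04 among members brighter than the median gene in either population) and from endothelial, smooth muscle and granulosa markers (p 2.00e-05), but they were singled out for their low medians, and the other lists go both ways or lie near the floor. Further macrophage and leukocyte genes had a median of −0.31 (18 of 21 below 0; brightness-matched random lists −0.16 to 0.11) and further steroidogenic genes −0.18 (5 of 8 below 0, led by Mgarp at −2.24; random lists −0.12 to 0.26). This is consistent with leukocytes and steroidogenic cells in the EGFP-low gate, with Lyz2 at 6.75 and Cyp11a1 at 8.76 in low arrays, although 6 of 27 leukocyte and 5 of 12 steroidogenic markers are also brighter in the high arrays than the median gene. Sorting was on EGFP, Star did not follow Cyp11a1 (0.33 against −4.74), and both a change within the epithelial cells and a part played by stroma, adipocytes or red cells stay open and untested.

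Log2 folds rose with brightness over genes (Spearman's rho = 0.291; trend −0.07 at the 10th and 0.13 at the 90th percentile). With the trend removed, camera called 12 lists, 11 of the 16 called before and the mitochondrially encoded genes. The trend may account for the olfactory call (median −0.10 to −0.04, adjusted p 0.397 after), the surface epithelium call (median 0.20 to 0.07, interquartile range 0.16, adjusted p 0.0826 after, but 0.0480 with the wrong C3 match that was corrected after seeing the data) and the immediate early, oxidative phosphorylation and ribosomal calls, of which 0 of 3 stayed. It is argued against as the whole source of the microRNA (0.0133) and small nucleolar (3.12e-05) calls and of the cell cycle, interferon, stem, steroidogenic, leukocyte and stroma calls, of which 6 of 6 stayed. What produced the trend was not tested, and no biological explanation of it was tested.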
